A study of Homo sapiens with 8 samples.

How the data were processed

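RNA-seq of MM1.S cells was analysed in 8 libraries, 2 for each of 4 groups: DMSO, MS177, MS177N1 and C24, each compound at 0.5 uM for 24 h. Per the labels' protocols, libraries were made from 1 ug of total RNA with the NEBNext Ultra II kit. The submitters' processing notes name the build hg19 and the tools STAR 2.4.2, Salmon 0.1.19 and DESeq2 1.38.2, with no role or order for each.

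The deposited values are log2 values for 16295 genes in 8 libraries, normalized by the authors per the file headers. From the values themselves, the scale is that of a variance-stabilizing transformation. They share a minimum of 5.967655733, the value of 0 reads. On that scale a doubling adds 0.23 from 10 reads and 0.60 from 100 reads, so differences of the deposited values understate the folds of low genes. The transformation was therefore inverted. All 130360 of 130360 recovered values were whole reads within 0.01, and the size factors recovered equalled median-of-ratios factors computed anew from the reads. The lowest number of reads per listed gene, summed over libraries, was 5. Of the names, 21 had the form of spreadsheet dates and 4 entries shared 2 names.

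The reads in listed genes ranged from 20000665 to 26619099 per library. The Pearson correlation of log2 values between the replicates of a group was between 0.996 and 0.998. The spread between replicates, as chi-square over degrees of freedom against counting noise, was 5.61 in DMSO, 7.38 in MS177, 2.45 in MS177N1 and 2.93 in C24. The median standard error of a log2 fold change was 0.11.

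Genes with at least 10 reads at the median library size in at least 2 libraries and at least 15 reads in all were tested. That left 14164 genes and left out 2131. The recovered reads divided by the authors' size factors, plus 1, were put on the log2 scale and fitted with limma 3.58.1 (trend and robust options, statmod 1.5.0) in R 4.3.3, with all 4 groups in 1 fit. The 6 pairwise comparisons were tested with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Folds of genes whose reads were all 0 in a group are not given, only levels. A count-based test had been planned, with this limma fit for a table that holds no counts. Because the deposited values are log2 values, the limma fit was used, on the recovered reads in place of the deposited values; this was settled before any call was seen.

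Lists of genes (33 lists, 1122 genes, of which 910 were measured) were tested with camera from limma at a preset correlation of 0.01 and again with a correlation estimated from the residuals, with Benjamini-Hochberg adjustment over the 32 lists with at least 5 measured members. With the estimated correlation, camera also uses the few residual degrees of freedom of the fit, so its p can rise without correlated members. For MYC targets in MS177 against DMSO the estimate was -0.0126, under the preset, yet the unadjusted camera p went from 3.61e-20 to 0.000286. A call lost with an estimated correlation is therefore not by itself a sign of correlation between members. For some lists the estimate was far above the preset: 0.481 for mitochondrially encoded genes, 0.423 for cytosolic ribosomal proteins and 0.390 for oxidative phosphorylation. The preset understates the correlation in these lists, so their camera p at the preset is too low in every comparison. The groups, comparisons, thresholds, most alternatives and the way of testing lists were chosen before the data were examined. The matching of 35 older gene symbols to list members was added after the first list results were seen; it moved the plasma-cell list from an adjusted p of 0.0632 to 0.0345 in MS177 against DMSO. Counts "adjusted over the list alone" use Benjamini-Hochberg adjustment within the list.

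Genes are named in the report by a fixed rule. It takes 11 genes of the study's subject; the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 2 CPM and no overlap between groups, for each compound against DMSO and for MS177 against MS177N1 and C24; and up to 4 called members with the largest changes for each called list. Other genes named are marked as chosen after their values were seen. Genes with near-identical copies or overlapping neighbours are called uncertain, since the counting could split or share their reads.

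The test was checked on simulated data with 200 changed genes in each of 5 simulations at this design. In MS177 against DMSO it found 47.2% of changes of 1.25-fold, 72.4% of 1.5-fold, 80.0% of 2-fold and 88.0% of 4-fold, with 47 false calls among 66744 unchanged genes. In C24 against DMSO these were 46.8%, 72.4%, 78.8% and 90.4%, with 50 among 66693. The simulations changed 200 genes, as many up as down, whereas 8207 genes were called in MS177 against DMSO and 13 in C24 against DMSO. They also gave all groups the same spread at a given read level, unlike the replicates here. The rates therefore need not hold for these data, and false calls are given over unchanged genes, not as a share of calls.

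The alternatives set beforehand were TMM scaling in place of the authors' size factors, no filter on low reads, only the 2 groups compared in the fit, the replicate number as a block, pseudocounts of 0.1 and 5, an estimated correlation for lists, and each library left out in turn. Added after the data were seen were the deposited values as they stand, limma voom on the recovered reads, total-read scaling, removal of each library's trend over transcript length and GC content, and list symbols as written. Overlaps between comparisons that share libraries were set against 20 simulations of unchanged groups. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads, exons and splice forms were not analysed, since the table holds a value per gene.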

Results

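RNA was sequenced from MM1.S cells, a human plasma-cell line from multiple myeloma. Cells were kept for 24 h with the solvent DMSO or with 0.5 uM of MS177, MS177N1 or C24, in 2 libraries per group and 8 in all. The series concerns degradation of EZH2, the histone methyltransferase of Polycomb repressive complex 2 (PRC2). From background knowledge, MS177 is a degrader that brings EZH2 to the ubiquitin ligase receptor CRBN, C24 is an EZH2 inhibitor from which it was made, and MS177N1 is a related control that does not degrade EZH2. The reads assigned to the 16295 listed genes numbered 20662196 and 23526036 in the DMSO libraries and 20000665 and 22817519 with MS177. They numbered 21426342 and 24813228 with MS177N1 and 26619099 and 20444106 with C24. Levels below are mean normalized reads ± SD over the 2 libraries of a group, and changes are limma log2 fold changes with their standard error (SE). In a principal component analysis the first component held 83.5% of the variance and set both MS177 libraries (55.5 and 57.0) apart from the other 6, which lay between -19.5 and -18.3. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

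The comparison of MS177 with DMSO asked which transcripts a degrader of EZH2 changes in myeloma cells. CDKN1A, which encodes the cell-cycle inhibitor p21, rose 4.70-fold, from 1097 ± 69.2 to 5162 ± 402 (n = 2 per group; log2 fold change 2.23, SE 0.07, limma adjusted p = 9.85e-13). MYC, a transcription factor that drives growth in myeloma, fell 1.88-fold, from 14715 ± 689 to 7827 ± 366 (-0.91, SE 0.05, limma adjusted p = 2.09e-10). EZH2 mRNA was 2681 ± 8.10 in DMSO and 2850 ± 43.3 with MS177 (0.09, SE 0.05, limma adjusted p = 0.155), so no change was called at the RNA level. Scaling by total reads put EZH2 past the threshold at 0.17, and removing the trend over transcript length and GC content turned it to -0.03. Of the partners of EZH2 in PRC2, EED fell by 0.57 (SE 0.08) and SUZ12 fell by 0.39 (SE 0.05), while the paralog EZH1 rose by 0.83 (SE 0.09). CRBN rose by 0.55 (SE 0.10), and IKZF1 and IKZF3, lymphoid transcription factors known as CRBN targets of immunomodulatory drugs, rose by 0.68 (SE 0.05) and 0.45 (SE 0.06). IRF4, a transcription factor on which plasma cells depend, fell by 0.26 (SE 0.04). The limma adjusted p of these 7 genes lay between 1.21e-08 and 0.000171, and CDKN1C, another cell-cycle inhibitor, was not called (-0.02, SE 0.13, adjusted p = 0.913).

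**Figure D1:**
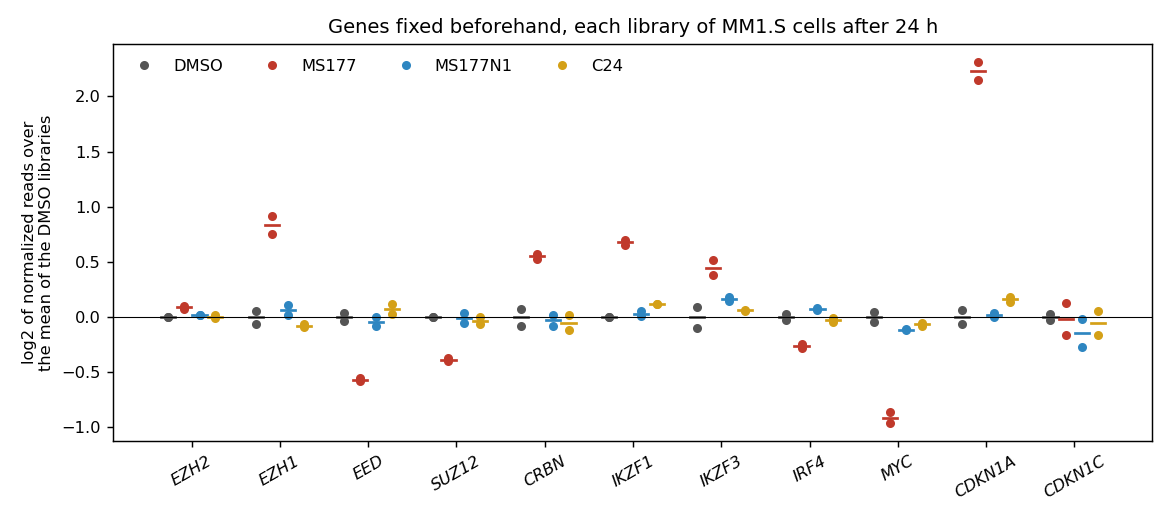
The vertical axis gives log2 of normalized reads over the mean of the DMSO libraries for the 11 genes fixed beforehand, with a point for each library and a bar for each group mean. With MS177, CDKN1A lies at 2.23 and MYC at -0.91, whereas no MS177N1 or C24 mean of these genes was past the threshold.

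Genes activated by the stress factor ATF4 rose together with MS177: 37 of 39 measured members rose and 0 fell (median log2 fold change 1.49, camera adjusted p = 2.07e-21). ATF3, a stress-induced transcription factor, rose 18.5-fold from 690 ± 15.1 to 12756 ± 311, and DDIT3, which encodes the pro-death factor CHOP, rose 16.6-fold from 169 ± 3.49 to 2826 ± 175. CHAC1, a glutathione-degrading enzyme, rose by 3.05 (SE 0.10) on the log2 scale, and PPP1R15A, which restores translation after stress, by 2.95 (SE 0.06). Of 28 genes induced by NF-kB, 23 rose and 1 fell (median 1.11, camera adjusted p = 2.91e-08), among them LTB, a lymphotoxin subunit, from 43.2 ± 12.1 to 638 ± 50.7. The cytokine subunit EBI3 rose from 1.92 ± 2.72 to 133 ± 35.3 and the prostaglandin synthase PTGS2 from 3.30 ± 4.67 to 93.6 ± 5.13, both from a few reads and with 1 DMSO library at 0. The member that fell was SOD2, the mitochondrial superoxide dismutase (-0.45, SE 0.06; chosen after its values were seen). Of 41 targets of p53, 26 rose and 2 fell (median 0.48, camera adjusted p = 4.68e-06). They included SESN2, a stress sensor upstream of mTORC1 (2.86, SE 0.07), BBC3, which encodes the death activator PUMA (2.85, SE 0.10), and the stress cytokine GDF15, from 4.67 ± 1.17 to 47.2 ± 5.95. With an estimated correlation the adjusted p was 0.00641 for the ATF4 list and 0.0283 for each of the NF-kB and p53 lists, so these 3 calls held. Lists share members, so their calls are not independent findings. SESN2 is also in the ATF4 list, and BBC3 and PMAIP1 are in the p53 and the apoptosis list. UNG is in the MYC and the G1/S list, and LDHA in the MYC and the glycolysis list.

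Genes of cell growth and division fell with MS177. Of 68 MYC targets, 63 fell and 1 rose (median -0.57, camera adjusted p = 5.77e-19; adjusted p = 0.00641 with an estimated correlation), with UNG, a uracil-DNA glycosylase, at -1.26 (SE 0.06) and TCOF1, a nucleolar factor of ribosome synthesis, at -1.05 (SE 0.05). Of 62 genes of G1/S and DNA replication, 54 fell and 1 rose (median -0.58, camera adjusted p = 7.80e-16; adjusted p = 0.0283 with an estimated correlation). UHRF1, which maintains DNA methylation at replication, fell 2.84-fold from 5089 ± 20.1 to 1793 ± 130, and CCNE1, the S-phase cyclin E1, fell 2.38-fold from 861 ± 144 to 358 ± 18.9. Of 65 genes of G2/M and mitosis, 47 fell and 1 rose (median -0.33, camera adjusted p = 9.01e-09), such as UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex (-1.09, SE 0.09). That list lost its call with the adjusted p = 0.123 with an estimated correlation. Of 26 genes of cholesterol synthesis and uptake, 21 fell and 0 rose (median -0.76, camera adjusted p = 9.01e-09; adjusted p = 0.0283 with an estimated correlation). The squalene epoxidase gene SQLE fell 3.11-fold, from 680 ± 54.8 to 218 ± 20.7.

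Energy, nucleotide and chaperone genes were lower in part. Of 21 glycolysis genes, 19 fell and 1 rose (median -0.58, camera adjusted p = 5.46e-08; adjusted p = 0.0754 with an estimated correlation); lactate dehydrogenase LDHA fell from 40733 ± 2096 to 21463 ± 413 and the glucose transporter SLC2A3 rose by 1.15 (SE 0.11). Of 43 nuclear genes of oxidative phosphorylation, 30 fell and 2 rose (median -0.34, camera adjusted p = 4.45e-07; adjusted p = 0.296 with an estimated correlation), with the complex I subunit NDUFS8 at -1.34 (SE 0.08). Of 22 genes of nucleotide synthesis and nutrient transport, 15 fell, such as the nucleotide kinase NME1 (-1.36, SE 0.05), and 7 rose, such as the amino acid transporter subunit SLC3A2 (1.07, SE 0.05); the median was -0.45 (camera adjusted p = 0.0270; adjusted p = 0.161 with an estimated correlation). Of 21 heat shock genes, 13 fell and 4 rose (median -0.39, camera adjusted p = 0.00386; adjusted p = 0.105 with an estimated correlation). HSPA8, the constitutive HSP70 chaperone, fell 2.82-fold, from 39440 ± 1765 to 13979 ± 927, and the collagen chaperone SERPINH1 rose 21.5-fold, from 43.2 ± 1.22 to 948 ± 18.4. Of 78 cytosolic ribosomal protein genes, 36 fell and 1 rose by small amounts (median -0.13, camera adjusted p = 0.000188; adjusted p = 0.505 with an estimated correlation). Under total-read scaling 15 of these fell and 3 rose, at a median of -0.04. RPS26, at -0.43 (SE 0.10), lost its call without MS177 replicate 2. The 13 mitochondrially encoded genes, a sign of RNA quality as well as of the organelle, fell in 10 cases and rose in 0 (median -0.51, camera adjusted p = 3.16e-05; adjusted p = 0.234 with an estimated correlation). Among them MT-CO3 (-0.52, SE 0.08) lost its call without MS177 replicate 1 or 2.

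Genes of plasma-cell identity moved both ways: of 48 measured, 25 fell and 13 rose (median -0.20, camera adjusted p = 0.0345; adjusted p = 0.185 with an estimated correlation). IGJ, the joining chain of polymeric immunoglobulin, fell 2.33-fold from 80328 ± 683 to 34409 ± 272, and FKBP11, a secretory pathway isomerase, fell by 1.44 (SE 0.06). CREB3L2, a membrane-bound transcription factor, rose by 1.24 (SE 0.06), and MBNL2, a splicing regulator, by 1.36 (SE 0.08). The list lost its call without DMSO replicate 2, without MS177 replicate 1 and with gene symbols taken as listed (adjusted p = 0.0632). MHC class II genes rose in 11 of 13 cases and fell in 2 (median 0.81, camera adjusted p = 0.00141; adjusted p = 0.161 with an estimated correlation), with the peptide loader HLA-DMB 2.83-fold higher (SE of log2 0.16). HLA-DRB1 (1.24, SE 0.10), HLA-DQA1 and HLA-DQB1 share reads with near-identical copies and are uncertain. HLA-DQA1 had 1 DMSO library at 0, and HLA-DQB1 lost its call without DMSO replicate 1 or MS177 replicate 1. Of 42 type I interferon genes, 24 rose and 10 fell (median 0.64, camera adjusted p = 0.00583; adjusted p = 0.185 with an estimated correlation). IFIT3, an antiviral effector, rose 9.33-fold from 28.9 ± 6.67 to 275 ± 2.39, while the ubiquitin-like modifier ISG15 fell 2.83-fold (SE of log2 0.22; chosen after its values were seen). Of 29 immediate early genes, 17 rose and 5 fell (median 0.59, camera adjusted p = 0.0015; adjusted p = 0.209 with an estimated correlation), led by SPRY2, an inhibitor of growth factor signalling, from 0.550 ± 0.778 to 48.7 ± 15.8. NR4A3, an orphan nuclear receptor, went from 1.03 ± 0.0985 to 19.5 ± 10.3 and lost its call without DMSO replicate 1 or 2 or MS177 replicate 1.

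Regulators of apoptosis rose in 17 of 35 cases and fell in 7 (median 0.24, camera adjusted p = 0.0143; adjusted p = 0.185 with an estimated correlation). BMF, a BH3-only death activator, rose 4.86-fold from 1993 ± 34.6 to 9700 ± 266, PMAIP1, which encodes NOXA, rose 3.57-fold, and the death receptor gene TNFRSF10B rose 2.48-fold. Markers of monocytes and granulocytes, listed as signs of another cell type, rose in 5 of 6 measured cases and fell in 0 (median 2.31, camera adjusted p = 0.0214; adjusted p = 0.161 with an estimated correlation). CD68, a lysosomal glycoprotein, rose 4.81-fold from 319 ± 52.3 to 1528 ± 80.4, whereas AIF1 went from 1.65 ± 2.33 to 46.8 ± 6.61 and CD163 from 0.481 ± 0.680 to 24.5 ± 0.234. That list lost its call without MS177 replicate 1, and CD163 lost its call without MS177 replicate 1 or 2. AIF1 and CD163 each had 1 DMSO library at 0.

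The lists closest to EZH2 itself were not called with MS177 in the fit used throughout, but for genes described as repressed by EZH2 this depended on the setting. Of 26 genes described as repressed by EZH2, 11 rose and 4 fell (median 0.33, camera adjusted p = 0.0585), and after removal of the length and GC trend 11 rose and 8 fell (median 0.16). That list was called as higher with no filter on low counts (adjusted p = 0.0271) and without DMSO replicate 1 (0.0377), and its adjusted p was 0.185 with an estimated correlation. Of 21 measured developmental PRC2 targets, 4 rose and 5 fell (median -0.20, camera adjusted p = 0.902). Of 12 PRC2 subunits, 3 rose and 7 fell (camera adjusted p = 0.153), and of 19 PRC1 subunits 8 rose and 3 fell (camera adjusted p = 0.336). Of 18 genes of the CRBN complex and its drug-induced substrates, 9 rose and 4 fell (camera adjusted p = 0.0937). The unfolded protein response had 14 members that rose and 23 that fell of 44 (camera adjusted p = 0.153), B cell genes 8 and 4 of 16 (0.0888; called at 0.0422 with no filter on low counts and at 0.0425 without DMSO replicate 1), MHC class I genes 3 and 6 of 17 (0.386), and replication-dependent histones 5 and 0 of 16 (0.0918). The NRF2 and xenobiotic list had 8 that rose and 8 that fell of 20 (0.871), other chromatin regulators 13 and 12 of 32 (0.907), T and NK cell markers 3 and 2 of 8 (0.805), and stromal and epithelial markers 2 and 2 of 8 (0.805). The erythroid list had 3 measured members and was not tested. For the T and NK list the median (-0.51) and the mean (0.43) differed in sign and the test pointed up, and for the stromal list the median was -0.18, the mean 0.57 and the test pointed down. For the NRF2 list the median was -0.07, the mean 0.15 and the test pointed down, and for other chromatin regulators these were -0.04, 0.05 and up. Scaling by total reads turned the median of the MHC class I, NRF2 and chromatin lists to 0.05, 0.02 and 0.05.

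**Figure D2:**
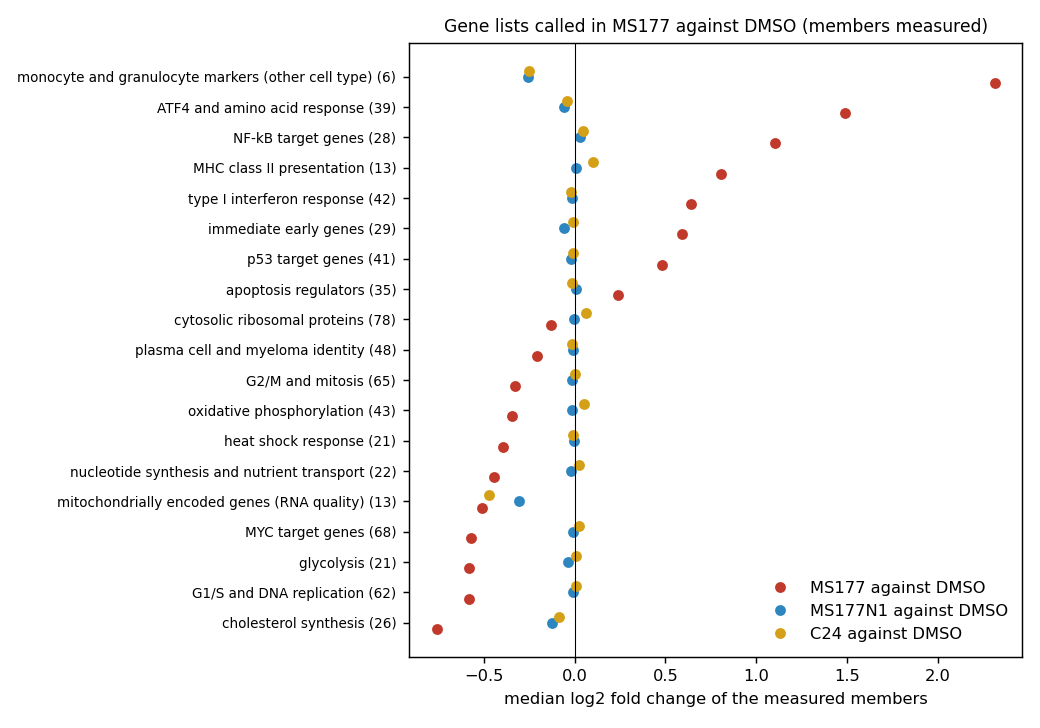
The horizontal axis gives the median log2 fold change of the measured members of the 19 lists called in MS177 against DMSO, with the number of members in brackets and a point for each compound against DMSO. The ATF4 list lies at 1.49 with MS177, at -0.06 with MS177N1 and at -0.04 with C24, and the mitochondrially encoded list lies at -0.51, -0.30 and -0.47.

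The largest rises with MS177 by the fixed rule started from a few reads. TMEM132A, a transmembrane protein gene, went from 2.06 ± 0.197 to 463 ± 69.9, BTN1A1, a butyrophilin, from 2.54 ± 0.483 to 393 ± 38.5, and LGALS3BP, a secreted galectin-binding protein, from 4.54 ± 1.74 to 534 ± 23.1. RCAN2, a calcineurin regulator, TACC2, a centrosomal protein, ITGA1, an integrin chain, UBD, a ubiquitin-like modifier, and CTTNBP2NL rose by 4.81 to 6.30 on the log2 scale. TNFAIP2, a gene induced by tumour necrosis factor, rose from 9.15 ± 8.86 to 1198 ± 3.50 and its DMSO libraries differed (15.4 and 2.88). XAF1, an antagonist of XIAP, went from 6.39 ± 5.92 to 170 ± 7.12, with 2.20 and 10.6 in DMSO. Among the largest falls, CBLN2, a synaptic organiser, went from 1308 ± 109 to 121 ± 3.94 (10.7-fold), SSBP4 from 569 ± 8.67 to 47.4 ± 10.2 (11.9-fold) and PIK3AP1, a B cell adaptor of PI3K, from 306 ± 40.4 to 28.5 ± 0.619 (10.4-fold). LRFN3, ABHD6, GREB1, RHBDL3 and CIDEB fell by 2.79 to 4.01 on the log2 scale. C11orf95 fell by 4.27 (5.31 without MS177 replicate 1 and 3.24 without MS177 replicate 2), and PVRIG fell by 5.22 but is uncertain because a pseudogene of near-identical sequence could take its reads. The limma adjusted p of these 20 genes lay between 3.49e-14 and 0.00541.

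In all, limma called 8207 of 14164 genes in MS177 against DMSO (57.9%; 4097 higher and 4110 lower), with 1364 at least 2-fold higher and 646 at least 2-fold lower. Of 32 lists tested, 19 were called (8 up and 11 down), and 6 held with an estimated correlation (ATF4, MYC, G1/S, NF-kB, p53 and cholesterol). Counts adjusted over the list alone were the same for 25 lists; for the other 7 they were 8 PRC2 subunits and 4 developmental targets that fell, 19 apoptosis regulators that rose, 24 unfolded protein response genes that fell, 0 ribosomal protein genes that rose and 30 that fell, 11 mitochondrially encoded genes that fell, and 4 histone genes that rose. The balance of calls depended on the correction used: 4761 higher and 3443 lower (58.0% higher) with total-read scaling, and 3604 higher and 4815 lower (42.8%) after removal of the length and GC trend. No called list changed direction of its median under TMM scaling, total-read scaling or that removal.

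**Figure D3:**
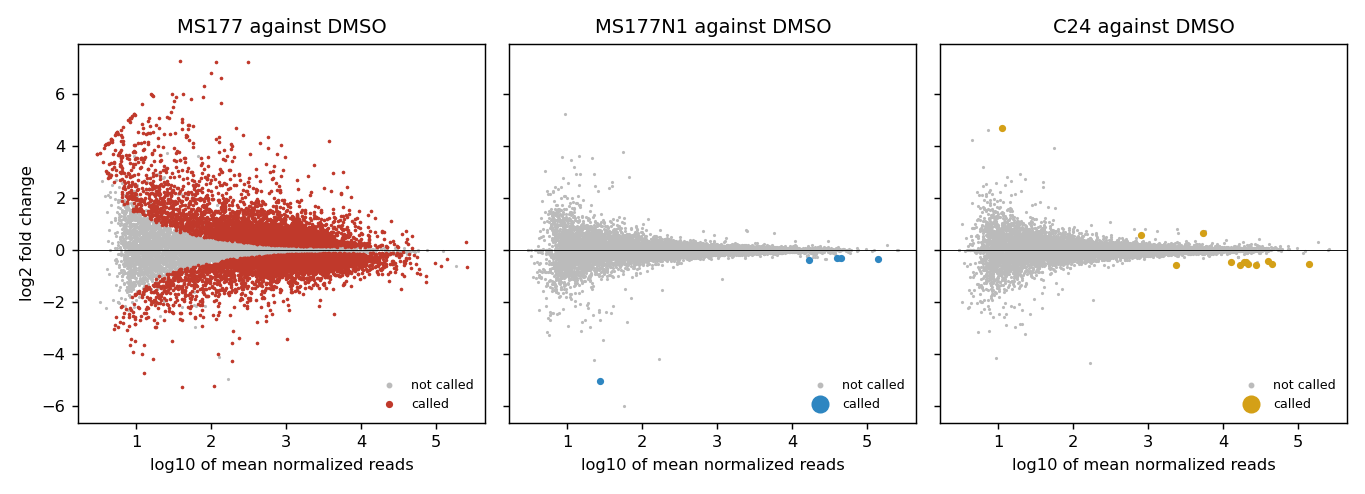
Each point is 1 of the 14164 genes tested, with log10 of its mean normalized reads on the horizontal axis and its log2 fold change against DMSO on the vertical axis, for MS177, MS177N1 and C24. Called genes are coloured and number 8207 with MS177, 5 with MS177N1 and 13 with C24.

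MS177N1 against DMSO measured a related compound that does not degrade EZH2. limma called 5 genes, 0 higher and 5 lower, and 718 genes had an unadjusted p under 0.05. MT-CO1, MT-CO2, MT-ND4 and MT-CYB, mitochondrially encoded subunits of the respiratory chain, fell by 0.34 (SE 0.05), 0.30 (SE 0.04), 0.33 (SE 0.05) and 0.38 (SE 0.06) with limma adjusted p of 0.0373, 0.00768, 0.0198 and 0.0356. MT-CO2 went from 47360 ± 639 to 38378 ± 1869 normalized reads. AMIGO3, a neuronal adhesion gene singled out after its values were seen, had 19.8 and 51.9 normalized reads in DMSO and 0 and 0 with MS177N1 (limma adjusted p = 0.00512); it overlaps GMPPB, so its reads are uncertain. None of the 11 fixed genes was called by limma: EZH2 was at 0.02 (95% interval -0.09 to 0.13), MYC at -0.11 (-0.21 to -0.01) and CDKN1A at 0.02 (-0.13 to 0.16). Of the 26 genes described as repressed by EZH2, 0 were called by limma and 2 had an unadjusted p under 0.05. The 95% interval lay within 2-fold for 11475 genes (81.0%).

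camera called 5 lists in MS177N1 against DMSO and 0 with an estimated correlation. The mitochondrially encoded list had 4 of 13 members that fell (10 adjusted over the list alone; median -0.30, camera adjusted p = 4.79e-22; adjusted p = 0.162 with an estimated correlation). Removing the length and GC trend left 0 of these 13 past the threshold at a median of -0.30. The other 4 lists had 0 members called by limma: cholesterol synthesis (median -0.12, camera adjusted p = 2.44e-07; 11 members at an unadjusted p under 0.05), ATF4 (-0.06, 0.000644; 15 members), NRF2 (-0.09, 0.00166; 5 members) and other chromatin regulators (0.06, 0.00166; 6 members). Their adjusted p with an estimated correlation was 0.162, 0.162, 0.230 and 0.286. Adjusted over the list alone, 1 cholesterol gene fell and 1 ATF4 gene rose and 4 fell. The number of genes called was 0 without DMSO replicate 2 or C24 replicate 2, 1 without C24 replicate 1, 19 without MS177 replicate 1 and 18 without MS177 replicate 2. The 4 mitochondrial calls were lost without either DMSO or C24 library and without MS177N1 replicate 1, and 3 of them, MT-CO1, MT-ND4 and MT-CYB, also without MS177N1 replicate 2. The ATF4 list lost its call without MS177N1 replicate 1, the NRF2 list without DMSO replicate 2, and the chromatin list without DMSO replicate 1 or MS177N1 replicate 2.

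C24 against DMSO measured the EZH2 inhibitor. DDIT4, a stress-induced inhibitor of mTORC1, rose 1.59-fold from 2559 ± 42.6 to 4074 ± 151 (0.67, SE 0.05, limma adjusted p = 1.59e-05). BHLHE40, a stress and clock transcription factor, rose 1.49-fold from 519 ± 38.0 to 773 ± 15.3 (0.58, SE 0.08, limma adjusted p = 0.00337). Mitochondrially encoded genes fell in 9 of 13 cases, from MT-CYB at -0.59 (SE 0.06) and MT-ND5 at -0.57 (SE 0.06) to MT-CO2 at -0.44 (SE 0.04), with limma adjusted p from 3.78e-05 to 0.00315. Of all 14164 genes, limma called 13, 3 higher and 10 lower, and 762 had an unadjusted p under 0.05. The other 2 were RP5-857K21.6, which went from 2901 ± 248 to 1928 ± 146, and PLA2G4B, a phospholipase named after its values were seen, with 0 and 0 normalized reads in DMSO and 18.8 and 32.1 with C24. PLA2G4B lies beside JMJD7 and shares read-through transcripts with it, so its reads are uncertain. None of the 11 fixed genes was called by limma: EZH2 was at 0.00 (95% interval -0.10 to 0.11), MYC at -0.07 (-0.17 to 0.03) and CDKN1A at 0.16 (0.01 to 0.31). Of the 26 genes described as repressed by EZH2, 0 were called by limma, 1 fell adjusted over the list alone, and 5 had an unadjusted p under 0.05. The 95% interval lay within 2-fold for 11443 genes (80.8%).

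camera called 7 lists in C24 against DMSO and 0 with an estimated correlation. The mitochondrially encoded list had a median of -0.47 (camera adjusted p = 7.24e-35; adjusted p = 0.218 with an estimated correlation; 10 fell adjusted over the list alone). Removing the length and GC trend left 3 of its 13 members called at a median of -0.55. The other 6 lists had 0 members called by limma and medians between -0.08 and 0.10: ribosomal proteins (16 members at an unadjusted p under 0.05), cholesterol synthesis (2), the unfolded protein response (6), MHC class II (1), oxidative phosphorylation (3) and MHC class I (1). Their camera adjusted p was 1.08e-10, 0.000224, 0.00163, 0.0106, 0.0113 and 0.0185, with 0.607, 0.294, 0.364, 0.381, 0.818 and 0.597 as the adjusted p with an estimated correlation. Adjusted over the list alone, 1 MHC class II gene rose. BHLHE40 lost its call without DMSO replicate 2 or either C24 library, MT-ND6 without DMSO replicate 1 or either C24 library, and RP5-857K21.6 without DMSO replicate 1 or C24 replicate 1. The number of genes called was 28 without MS177 replicate 1 and 27 without MS177 replicate 2, and the number of lists was 4 without DMSO replicate 2, where MHC class I, the unfolded protein response and oxidative phosphorylation lost their calls. MHC class I also lost its call without C24 replicate 2, MHC class II without DMSO replicate 1, and oxidative phosphorylation without C24 replicate 1.

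**Figure D4:**
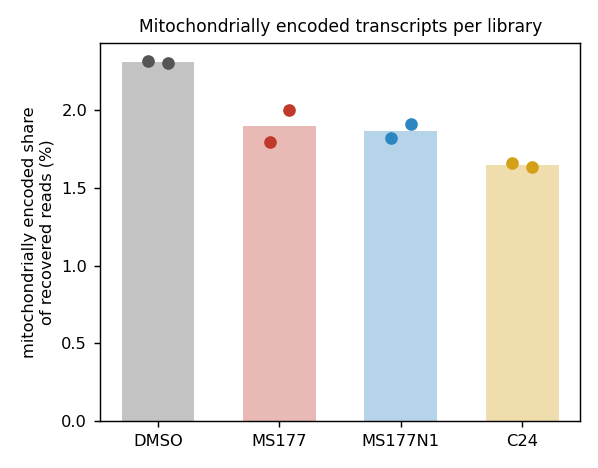
The vertical axis gives the percentage of reads in mitochondrially encoded genes, with a bar for the mean of each group and a point for each library. The DMSO libraries lie at 2.32% and 2.31%, above the means of MS177 (1.90%), MS177N1 (1.87%) and C24 (1.65%).

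MS177 against MS177N1 tested the degrader directly against its non-degrading relative at the same dose and time. The stress genes ATF3 and DDIT3 were higher with MS177 by 4.23 (SE 0.07) and 4.03 (SE 0.11) on the log2 scale, CDKN1A by 2.22 (SE 0.07) and BMF by 2.28 (SE 0.05). MYC was lower by -0.80 (SE 0.05, limma adjusted p = 9.67e-10) and UHRF1 by 2.83-fold (SE of log2 0.06). EZH2 was at 0.07 (95% interval -0.04 to 0.17, limma adjusted p = 0.283), with 0.14 and a call under total-read scaling and -0.05 after removal of the length and GC trend. Of 39 ATF4 genes 36 were higher and 0 lower (median 1.51, camera adjusted p = 2.11e-22), of 68 MYC targets 63 were lower and 1 higher (-0.57, 3.33e-19), and of 62 G1/S genes 54 were lower and 2 higher (-0.58, 1.86e-15). Of 41 p53 targets 27 were higher and 3 lower (0.50, 2.89e-06), of 28 NF-kB genes 23 were higher and 1 lower (1.03, 2.31e-08), and of 26 cholesterol genes 18 were lower and 0 higher (-0.61, 4.72e-07). Adjusted over the list alone these counts were the same for ATF4, MYC and NF-kB; for G1/S they were 54 and 3, for p53 27 and 4, and for cholesterol 19 and 0. With an estimated correlation the adjusted p was 0.00587 for ATF4 and MYC, 0.0328 for G1/S, p53 and NF-kB and 0.0464 for cholesterol, and the other 12 of the 18 called lists lost their calls, at an adjusted p from 0.0883 to 0.515.

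MS177 against C24 tested the degrader directly against the inhibitor. ATF3 and DDIT3 were higher with MS177 by 4.09 (SE 0.07) and 3.73 (SE 0.11), CDKN1A by 2.07 (SE 0.07) and BMF by 2.27 (SE 0.05), while MYC was lower by -0.84 (SE 0.05, limma adjusted p = 4.99e-10). EZH2 was at 0.08 (95% interval -0.02 to 0.19, limma adjusted p = 0.174), with 0.17 and a call under total-read scaling and -0.03 after removal of the length and GC trend. CCND1, the G1 cyclin D1, was lower with MS177, at 34.7 ± 5.14 against 248 ± 16.6 with C24. Of 39 ATF4 genes 36 were higher and 0 lower (37 and 0 adjusted over the list alone; median 1.47, camera adjusted p = 2.09e-21), and of 68 MYC targets 63 were lower and 1 higher (-0.59, 8.95e-20). The mitochondrially encoded list was not called (median -0.05, camera adjusted p = 0.734), with 2 members higher and 3 lower with MS177 (2 and 2 adjusted over the list alone); its median was 0.04 under total-read scaling and 0.13 after removal of the length and GC trend. Of 17 lists called, the same 6 as against DMSO held with an estimated correlation, with adjusted p between 0.00641 and 0.0408, and the other 11 lost their calls at an adjusted p from 0.0797 to 0.385.

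limma called 8131 genes in MS177 against MS177N1 (4077 higher and 4054 lower) and 8233 in MS177 against C24 (4120 higher and 4113 lower). In all 3 comparisons of MS177, 7011 genes were called in the same direction (3442 higher and 3569 lower) and 0 in mixed directions. All 3 use the same MS177 libraries against groups with few calls between them, so this agreement is not independent support. Of the 10 largest rises against DMSO, 7 were also among the 10 largest against MS177N1 and 9 against C24, and of the 10 largest falls 9 and 8. Against MS177N1 the others were INHBE, an activin subunit, SERPINH1, UTS2R and RP11-512M8.5. RP11-512M8.5 had 192 and 7.48 normalized reads with MS177, 0 and 0 with MS177N1 and 64.9 and 60.6 in DMSO. It lost its call without either MS177N1 library. Against C24 they were SYNPO2L, RAB3A and CCND1. TNFAIP2 had 15.7 and 0.909 normalized reads in the 2 MS177N1 libraries, and against C24 it lost its call without C24 replicate 1. Mitochondrially encoded genes lost their list call against MS177N1 without MS177 replicate 1 or MS177N1 replicate 2, nucleotide synthesis without MS177 replicate 1, and the monocyte and granulocyte list lost it against C24 without MS177 replicate 1.

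MS177N1 against C24 compared the non-degrading relative with the inhibitor. DDIT4 was lower with MS177N1, at 2910 ± 43.5 against 4074 ± 151 (-0.49, SE 0.05, 95% interval -0.60 to -0.37, limma adjusted p = 0.00136). With MS177 it reached 11759 ± 602, and MS177N1 against DMSO was at 0.19 (SE 0.05, limma adjusted p = 0.965). The only other gene called was AMIGO3, at 0 and 0 with MS177N1 and 22.3 and 25.4 with C24 (limma adjusted p = 0.00767), so limma called 2 genes, and 634 had an unadjusted p under 0.05. BHLHE40, called with C24 against DMSO, did not differ past the threshold between MS177N1 and C24 (-0.24, SE 0.08, limma adjusted p = 0.997). The 95% interval of the difference lay within 2-fold for 11504 genes (81.2%) and within 1.5-fold for 9908 (70.0%). For EZH2 it ran from -0.09 to 0.13, for MYC from -0.14 to 0.05 and for CDKN1A from -0.29 to 0.00. DDIT4 lost its call without any 1 of the MS177N1 or C24 libraries. The number of genes called was 0 without either C24 library, 1 without MS177N1 replicate 1, 13 without MS177 replicate 1 and 11 without MS177 replicate 2.

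camera called 11 lists between MS177N1 and C24, and 0 with an estimated correlation, where the lowest adjusted p was 0.309. The mitochondrially encoded list was higher with MS177N1 (median 0.18, camera adjusted p = 1.67e-13; adjusted p = 0.309 with an estimated correlation), with 0 members called by limma, 9 at an unadjusted p under 0.05 and 9 adjusted over the list alone. The ribosomal protein list was lower (median -0.07, camera adjusted p = 9.66e-15; adjusted p = 0.474 with an estimated correlation), with 0 members called and 9 at an unadjusted p under 0.05. The other 9 lists had medians between -0.12 and 0.04 and no member called by limma but DDIT4 in the ATF4 list; their adjusted p with an estimated correlation ran from 0.309 to 0.606. Lists called numbered 5 without MS177N1 replicate 1, 3 without MS177N1 replicate 2, 2 without C24 replicate 1 and 8 without C24 replicate 2.

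The 3 comparisons with DMSO share the same 2 control libraries, so unchanged groups were simulated against them 20 times. These simulations hold no effects, so few calls and little overlap can arise in them, and the numbers for independent lists leave out the shared controls; neither alone is a null value for an overlap with the long MS177 list. MS177 and C24 shared 13 genes called in the same direction (3 higher and 10 lower), against a mean of 0.350 and at most 2 with unchanged groups and 0.868 and 2.90 for independent lists. MS177 and MS177N1 shared 4 genes (0 higher and 4 lower), with a mean of 0.500 and at most 4 in the simulations and 1.45 lower genes for independent lists. MS177N1 and C24 shared 4 genes, the mitochondrially encoded MT-CO1, MT-CO2, MT-ND4 and MT-CYB, with a mean of 0.500 and at most 4 in the simulations and 0.00353 lower genes for independent lists. The covariance of log2 fold changes across genes was 0.0672 for MS177 and C24 (simulated 0.0554), 0.0601 for MS177 and MS177N1 (0.0546) and 0.0658 for MS177N1 and C24 (0.0552). Pearson's r across genes, which are not independent replicates, was 0.21, 0.18 and 0.53, with 0.51, 0.50 and 0.51 simulated. A split of the controls would leave 1 library on each side, so they were not split. The simulations gave all groups the same spread per gene. Between replicates the spread, as chi-square over degrees of freedom, was 5.61 in DMSO and 7.38 in MS177. In MS177N1 it was 2.45 and in C24 2.93. The simulated covariance may therefore be too low, and part or all of the excess may come from the shared controls. MS177 against MS177N1 and against C24, which use the same MS177 libraries, shared 7387 genes. The numbers for independent lists were 1186 higher and 1177 lower, and the covariance was 0.805 (simulated 0.0543). The overlap of MS177 with MS177N1 was 0 without DMSO replicate 2, MS177N1 replicate 1 or either C24 library, 2 without MS177N1 replicate 2 and 13 without either MS177 library; that of MS177N1 with C24 was 0 without the first 4 of these, 1 without MS177N1 replicate 2 and 12 without either MS177 library.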

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

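Total-read scaling, removal of the length and GC trend, limma voom, the deposited values as they stand and list symbols as written were chosen after the data were seen; the other alternatives were planned, except that TMM replaced the authors' size factors as the scaling alternative because those factors are in the deposited values. The planned DESeq2 Wald test was not run. Calls in MS177 against DMSO numbered 7293 to 8419 over all alternatives, and none of the 298 called values of named genes changed direction; 0 to 12 lost their call per alternative. With total-read scaling the median log2 fold change of MS177 against DMSO was 0.0877, against 0.00447 with the authors' size factors. Where a library is left out, the lone sample is assumed to vary like the other groups. In the main fit the 4 groups share 1 estimate of the spread per gene. Replicate spread was higher in MS177 (7.38) and DMSO (5.61) than in C24 (2.93) and MS177N1 (2.45). With only the 2 groups in the fit, MS177 against DMSO had 7408 calls in place of 8207, and MS177N1 against C24 had 28 in place of 2. The p-values of a comparison thus rest in part on the spread of other groups.

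Genes called in MS177N1 against DMSO (5) numbered 17 with only the 2 groups in the fit, 9 with a pseudocount of 5, 8 on the deposited values, 8 with voom, 3 with total-read scaling and 0 to 19 with a library left out. Those in C24 against DMSO (13) numbered 10 to 28 with a library left out, and those in MS177N1 against C24 (2) numbered 28 with only the 2 groups in the fit, 1 with a pseudocount of 5 and 0 to 13 with a library left out. The overlap of MS177 and MS177N1 against DMSO (4) was 9 with only the 2 groups in the fit, 7 with a pseudocount of 5, 7 on the deposited values, 7 with voom, 2 with total-read scaling and 0 to 13 with a library left out. That of MS177 and C24 (13) was 8 after removal of the length and GC trend. That of MS177N1 and C24 (4) was 11 with only the 2 groups in the fit, 7 with a pseudocount of 5, 7 on the deposited values, 7 with voom, 2 with total-read scaling, 1 after removal of the length and GC trend and 0 to 12 with a library left out. The cause was not tested.

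With the replicate number as a block, 11 genes were called in MS177N1 against DMSO, 20 in C24 against DMSO and 8299 in MS177 against DMSO, and both overlaps of 4 became 9. Deviations of same-numbered replicates correlated between -0.14 (DMSO and C24) and 0.22 (DMSO and MS177) over 11183 genes. The fit without a block was set beforehand, since nothing in the labels marks the numbers as pairs. These correlations do not exclude a replicate effect shared by some of the groups. Lists called with an estimated correlation numbered 6 in each comparison of MS177 (of 19, 18 and 17) and 0 in the other 3 (of 5, 7 and 11). With a library left out, lists numbered 4 to 8 in C24 against DMSO and 2 to 11 in MS177N1 against C24. Lists gained calls too. In MS177 against MS177N1 with no filter on low counts, genes described as repressed by EZH2 and B cell genes were called as higher (adjusted p = 0.0482 for both) and plasma-cell identity as lower (0.0406; 0.0433 without MS177 replicate 2). In MS177N1 against DMSO the ribosomal protein list was called as higher without DMSO replicate 1 (0.0420) and as lower without DMSO replicate 2 (0.00388), the unfolded protein response as lower without DMSO replicate 1 (0.0420) and immediate early genes as lower without DMSO replicate 2 (0.0436). MYC targets were called as higher in C24 against DMSO without either MS177 library (0.0303 for both), and in MS177N1 against C24 MHC class II was called as lower with no filter on low counts (0.0344) and developmental PRC2 targets as lower without C24 replicate 2 (0.0277). The cause was not tested.

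Values of uncalled genes changed sign. After removal of the length and GC trend EZH2 was at -0.0281 in MS177 against DMSO, -0.0542 against MS177N1 and -0.0266 against C24, and at -0.0015 in C24 against DMSO; CDKN1C in MS177 against DMSO was at 0.0753, and at 0.0654 with total-read scaling. With total-read scaling SUZ12 in MS177N1 against DMSO was at 0.0012, and EZH2 in MS177 passed the threshold at 0.17 against DMSO, 0.14 against MS177N1 and 0.17 against C24. The cause was not tested.

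Leaving out each library in turn gave these ranges of log2 fold changes that crossed 0: CDKN1C in MS177 against DMSO -0.164 to 0.125, EED in MS177N1 against DMSO -0.0834 to 0.0022, SUZ12 in MS177N1 against DMSO -0.0504 to 0.0329, CRBN in MS177N1 against DMSO -0.106 to 0.0483, CDKN1A in MS177N1 against DMSO -0.0473 to 0.0813, EZH2 in C24 against DMSO -0.0086 to 0.0170, CRBN in C24 against DMSO -0.124 to 0.0296, IKZF3 in C24 against DMSO -0.0297 to 0.155, CDKN1C in C24 against DMSO -0.164 to 0.0546, CDKN1C in MS177 against MS177N1 -0.0182 to 0.271, CDKN1C in MS177 against C24 -0.109 to 0.18, SUZ12 in MS177N1 against C24 -0.0157 to 0.0676, CRBN in MS177N1 against C24 -0.0487 to 0.0861 and CDKN1C in MS177N1 against C24 -0.214 to 0.0334. Fewer samples were in these fits.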

Other observations

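The lists of this paragraph and the next were written, and the genes named from them chosen, after the data were seen. Members such as TXNIP and BMF had already been seen to rise in the fixed lists. The camera p-values, adjusted over these added lists alone, are therefore descriptive and give no independent support. Of 25 genes activated by FOXO transcription factors, 19 rose and 1 fell with MS177 against DMSO (median log2 fold change 0.69, camera adjusted p = 2.30e-08; adjusted p = 0.0210 with an estimated correlation). PIK3IP1, an inhibitor of PI3K, went from 332 to 1988 normalized reads and TXNIP, an inhibitor of glucose uptake, from 3169 to 16814. Of 32 autophagy genes, 20 rose and 3 fell (median 0.39, camera adjusted p = 7.27e-05; adjusted p = 0.0260 with an estimated correlation), among them the autophagosome gene GABARAPL1, from 208 to 567. Of 16 circadian clock genes, 12 rose and 0 fell (median 0.72, camera adjusted p = 5.58e-05; adjusted p = 0.0260 with an estimated correlation), with PER1 from 544 to 2032 and NR1D1 from 470 to 1539.

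Of 31 proteasome subunit genes, 27 fell and 0 rose with MS177 against DMSO (median -0.45, camera adjusted p = 7.96e-10; adjusted p = 0.0731 with an estimated correlation), such as the catalytic subunit PSMB5 at -0.73. Of 58 mitochondrial ribosomal protein genes, 43 fell and 2 rose (45 and 3 adjusted over the list alone; median -0.37, camera adjusted p = 2.30e-08; adjusted p = 0.169 with an estimated correlation). Of 30 tubulin and actin genes, 20 fell and 5 rose (median -0.34, camera adjusted p = 0.000122; adjusted p = 0.213 with an estimated correlation), and of 39 lysosome genes 14 rose and 14 fell (camera adjusted p = 0.958). Lists not given here for MS177N1 or C24 against DMSO had no call except the tubulin and actin list in MS177N1 (camera adjusted p = 1.63e-05; adjusted p = 0.390 with an estimated correlation), with 0 members called by limma.

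Of the tests below, those of shared DMSO libraries, of degradation in MS177N1 and MS177, of monocyte admixture and of chaperones were chosen after the results were seen, as was the use of a 95% interval to judge the low-baseline test. Mitochondrially encoded transcripts were lower than in DMSO with each compound. With C24, a Spearman rho of -0.0204 between log2 fold change and transcript length over 10057 nuclear genes argues against RNA degradation. The median of the 13 genes was -0.47 under TMM and total-read scaling, which argues against the choice among these scalings as the cause. Both lay close to the authors' factors here, with a median over all genes of 0.00066 and 0.00048 against 0.00156. An error common to all of these scalings was not tested. With MS177N1 rho was 0.210, past the bound set for degradation that differs between libraries, and with MS177 it was 0.190, between the bounds set. For MS177N1 against C24, however, rho was 0.248 while the mitochondrially encoded list was higher with MS177N1 (median 0.18). Removal of the length and GC trend left the median of MS177N1 against DMSO at -0.296 (-0.304 before), with 0 of 13 called (4 before). For MS177 against DMSO it left the median at -0.368 (-0.509 before), with 9 of 13 called as lower (10 before). Degradation thus stays open for MS177N1 and MS177. A chance deviation of the 2 DMSO libraries that all comparisons with DMSO share stays open, as does an effect of the compounds, which was not tested. The camera adjusted p of the list in C24 against DMSO, 0.218 with an estimated correlation, cannot decide on a chance deviation. That p does not measure a deviation of the DMSO libraries, and 0 of the 32 lists were called with an estimated correlation in C24 against DMSO.

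More genes were at least 2-fold higher than lower with MS177 against DMSO (ratio 2.11). The ratio was 1.78 after removal of the length and GC trend (1185 higher and 667 lower, lower 95% limit 1.62), and 2.02 under TMM and 2.85 under total-read scaling, which argues against these as the whole cause. Among the 8270 genes with a mean over all 8 libraries of at least 300 normalized reads it was 1.59 (342 and 215, 95% interval 1.34 to 1.89). That ratio lies above the bound of 1.5 set beforehand against a low baseline of the genes that rose, but its interval reaches below the bound. The mean also includes the MS177 libraries, so a gene low in DMSO can pass through its rise with MS177. The test therefore cannot decide, and a low baseline may account for part of the ratio and stays open.

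Markers of monocytes and granulocytes rose with MS177 in a cell line. CD14, FCER1G, VCAN and CSF1R together went from 16.4 to 19.5 normalized reads. The upper 95% limit of their rise, by counting error, was 11.4 reads. That was 0.943% of the rise of CD68, which was 1209 reads. This argues against an admixture of cells that express CD14, FCER1G, VCAN and CSF1R as the source of the CD68 rise. S100A9 and ITGAM, which also rose in the list, were not in the test, so an admixture of cells without the tested genes stays open. The limit is not small beside AIF1 (3.30 and 0 in DMSO, 51.4 and 42.1 with MS177) or CD163 (0 and 0.961, 24.6 and 24.3). For these genes the test cannot decide. A change of the MM1.S cells themselves stays a hypothesis, found and tested on the same data.

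The rise of ATF4-linked genes with MS177 could come from unfolded proteins in the endoplasmic reticulum, and this stays open. Of 8 chaperone genes of that response, 1 rose, DNAJB9 (0.89), and 7 fell, from HSPA5 at -0.15 to SDF2L1 at -1.47. In the whole list of 44 genes 14 rose and 23 fell (camera adjusted p = 0.153), and the sensor genes ERN1 (1.39) and EIF2AK3 (0.61) and the degradation factor gene HERPUD1 (1.52), chosen after their values were seen, were among those that rose. Other triggers of ATF4 were not tested.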
